A study of Mus musculus with 6 samples.

How the data were processed

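Regulatory T cells (Treg cells), here CD4+ cells that express the transcription factor Foxp3, were sorted by flow cytometry from healthy female C57BL/6 mice, per the labels. Total RNA that included small RNAs was extracted with a miRNeasy kit, TruSeq RNA libraries were made, and sequencing was done on a HiSeq 2500, per the labels' protocols. The series holds 6 libraries in 2 groups of 3: a wild-type group (WT) and a group with a miR-27 transgene (miR-27 Tg), with replicates numbered 1 to 3 in each. The genotype label of the control group reads WT Tg, and what that wording denotes is not given in the sources used here. Nothing in the labels says that the 3 libraries of a group came from separate mice, so p-values measure only the spread between these libraries, which may be technical.

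The authors deposited 1 table of RPKM values that covers all 6 libraries. STAR version 2.2.0c and HOMER, with the genome builds mm10 and GRCm38, are named per the submitters' processing notes. HOMER counted reads in the exons of RefSeq transcripts of mm10 on both strands, and wrote them as RPKM with library totals set to 10000000 reads, per the file headers. The deposited RPKM values are therefore per kilobase and per 10000000 reads counted over the 34711 transcripts of the table. In every library the product of RPKM and length in kilobases summed to that total. A read in an exon that several transcripts share was counted once for each of them. Because both strands were counted, reads of overlapping genes on opposite strands cannot be told apart. Other annotated genes share 40.0% of the exonic bases of Il12rb2, 49.1% of Bcl2a1b, 26.7% of Fdps, 25.9% of Ifng and 21.5% of Mmd, so their values are uncertain too. How reads with several genomic positions were treated is not given in the sources used here, so values of near-identical genes (Hspa1a and Hspa1b, the haemoglobin genes, Ly6c1 among its family) are uncertain.

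Low values gave the depth. Among 3866 to 4104 low values per library, on transcripts of 200 to 4000 bases, 100% were whole multiples, within 0.1 of a read, of the value of 1 read. On a transcript of 1 kilobase that value was 0.238, 0.254 and 0.265 RPKM in WT replicates 1 to 3 and 0.263, 0.290 and 0.290 in miR-27 Tg replicates 1 to 3. It corresponds to 42100000, 39300000 and 37700000 counted reads in WT and to 38100000, 34400000 and 34400000 in miR-27 Tg. Read numbers given for single transcripts come from this step. RPKM values are not counts, and no count model was used. Transcripts of under 200 bases reach a high RPKM with few reads, so their values carry large counting error.

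From the deposited values 1 transcript per gene symbol was kept, the one with the highest mean RPKM over all libraries (24453 symbols, of which 5612 had several transcripts). The 13621 genes with a mean RPKM of at least 1 were tested. The RPKM values were analysed as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, as a moderated linear model with an intensity trend (limma-trend), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. No replicate block was used, since nothing in the labels says that equal replicate numbers mark a shared litter, day or batch. Every fold change is on the log2(RPKM + 1) scale, which understates the change of genes with low values. Levels are mean ± SD of RPKM.

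Gene lists were fixed before the data were examined. They cover the miR-23/27/24 loci, miR-27 targets named for T cells and for other cells, Treg core, suppressor, effector, resting, homing, helper T, TGF-beta, NF-kB, interferon, cholesterol, glycolysis, cell cycle, apoptosis, immediate-early and ribosomal protein genes, and markers of B cells, myeloid cells, CD8 T and NK cells, erythroid cells and mitochondrial transcripts. Each was tested with camera, with a preset correlation between genes of 0.01 and then with an estimated correlation, and with fry, which tests whether a set moves on balance one way and compares it with no other genes (all from limma), adjusted over the lists by Benjamini-Hochberg. Of 13 mitochondrially encoded genes 0 matched a symbol of the table, so that list has no values, and Ighm, Ighd and Ahsp were not matched either. Folr4 and Emr1, older symbols of Izumo1r and Adgre1, were counted under the newer symbols.

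For the seed analysis the 3′ UTR of the longest annotated transcript with a 3′ UTR was taken from GENCODE M21 (GRCm38), and the match to bases 2 to 8 of miR-27 was searched in it. Genes with no annotated 3′ UTR counted as not searched. Genes with a site were compared with the others by the difference in median log2 fold change, by camera and against 10000 random gene sets matched on 3′ UTR length (10 bins) and mean expression (5 bins). Seeds of 9 other microRNAs were searched in the same way.

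The rule for the genes named was also fixed before the data were examined. It takes up to 12 genes per direction with the largest fold change among those past the threshold with non-overlapping groups, then Foxp3, the miR-23/27/24 loci and every miR-27 target named for T cells. It adds up to 4 members of each list with the smallest p, and up to 6 lower genes with a miR-27 site. Predicted genes without a name, Y-linked genes and antigen receptor segments were counted, but named only where no other gene filled the place. Some genes that the rule takes are not reported here. A further set of genes, described with the other observations, was chosen after its values were seen.

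The fit was tested on simulated data made from the means and residual spread of the 13621 genes, in 10 draws. It recovered 16.1% of genes changed by 0.5 on the log2 scale, 59.6% of those changed by 1 and 90.8% of those changed by 2. Of 1254 calls 57 (4.55%) fell on genes that had not been changed. Camera found a list of 30 genes with a log2 change of -0.6 in 10 of 10 draws and a seed change of -0.06 in 10 of 10. Of 200 random lists 6 passed. These camera results were counted at an unadjusted p under 0.05. Simulated genes varied independently of each other, which genes of a real list need not do.

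Alternatives covered the pseudocount, the filter on low values, the scaling, a replicate block, library weights, the variance model, the choice of transcript, the definition of a site, the correlation in camera, a looser threshold, and leaving out each library. Transcripts of under 200 bases left out, and a myeloid marker level (the mean of the marker list) as a covariate, were alternatives chosen after seeing the data. That covariate removes the mean change of the marker list by construction, so it tests other genes and lists and not the markers. Site searches and figures used Python 3.11.15, NumPy 2.4.6 and Matplotlib 3.10.9.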

Results

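RNA was sequenced from sorted CD4+Foxp3+ Treg cells, the lymphocytes that restrain immune responses, in 3 WT and 3 miR-27 Tg libraries. MicroRNAs such as miR-27 repress messenger RNAs through short matches in their 3′ UTRs, and the series text describes overexpression of miR-27a specific to Treg cells, in mice it names Foxp3cre het. Depth was 37700000 to 42100000 counted reads in WT and 34400000 to 38100000 in miR-27 Tg. Pearson correlations of log2 levels across genes, which are not independent replicates, were 0.979 to 0.985 within groups and 0.970 to 0.980 between them.

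The first comparison asked whether the libraries carry the overexpression that their labels name. Mir27a (NR_029746), the hairpin of miR-27a on chromosome 8 from 84208672 to 84208758 (mm10, plus strand), had 29.3 ± 7.88 RPKM in WT and 8089 ± 754 in miR-27 Tg (SD, n = 3). It rose by 8.09 on the log2 scale (SE 0.17, adjusted p = 6.05e-07 by limma), with 9, 13 and 8 reads in WT and 2921, 2206 and 2339 in miR-27 Tg, so each library matched its label. These reads of long-RNA libraries do not measure the mature microRNA.

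Neighbouring hairpins of the same cluster did not pass the test: Mir23a had 13.3 ± 9.46 and 12.3 ± 8.70 RPKM in WT and miR-27 Tg (adjusted p = 0.987), and Mir24-2 had 27.4 ± 11.4 and 8.43 ± 9.86 (0.225). The homologous cluster on chromosome 13 had log2 fold changes of 1.63 for Mir23b (adjusted p = 0.0845), 1.80 for Mir27b (0.172) and 1.92 for Mir24-1 (0.115), from 2 to 35 reads per library. Other annotated transcripts cover 100% of the bases of Mir27b and of Mir24-1 and 79.4% of those of Mir24-2, so their reads were not told apart. Mir24-2 passed without miR-27 Tg replicate 1 (log2 fold change -2.85, adjusted p = 0.0259), and Mir23b (1.98, 0.0480) and Mir27b (2.43, 0.0368) passed without miR-27 Tg replicate 2. Of these 6 loci 1 rose, and 4 rose and 1 fell when adjusted over the list alone. The loci as a list gave adjusted p = 0.0183 by fry, adjusted p = 7.76e-05 by camera and adjusted p = 0.265 with an estimated correlation.

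The second comparison asked which genes differ between miR-27 Tg and WT Treg cells. Effector molecules were among the genes that fell most. Itgae (NM_008399, mm10 chromosome 11, 73090595 to 73147449), the integrin chain CD103 that anchors T cells to epithelium, fell by 2.05 on the log2 scale, from 331 ± 60.7 RPKM in WT to 78.8 ± 11.1 in miR-27 Tg (n = 3, SE 0.16, adjusted p = 0.00534 by limma). Gzmb, the cytotoxic protease granzyme B, fell by 2.02, from 145 ± 60.3 to 34.3 ± 12.1 RPKM (SE 0.33, adjusted p = 0.0395). Oas2, an interferon-induced sensor of double-stranded RNA, rose by 2.11, from 44.2 ± 4.58 to 193 ± 18.9 RPKM (SE 0.12, adjusted p = 0.000683). Foxp3 did not pass the test, with 764 ± 89.9 and 836 ± 104 RPKM (log2 fold change 0.13, SE 0.13, adjusted p = 0.750), and neighbouring genes share 31.5% of its exonic bases.

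In all, 51 genes were higher and 89 lower in miR-27 Tg among 13621 tested by limma, and 25 rose and 55 fell at least 2-fold. The groups did not overlap for any of these 140 genes, nor for 18.5% of all genes tested, against 10% by chance. Among the genes that rose most, Ifitm3, which restricts the entry of viruses, went from 20.48 ± 8.37 to 70.8 ± 15.8 RPKM (log2 fold change 1.78, adjusted p = 0.0326). With the myeloid marker level, described below, as a covariate the log2 fold change of Ifitm3 was 0.97, so a source in myeloid RNA was not excluded for it. Itgam, the integrin chain CD11b of myeloid cells, went from 4.41 ± 0.487 to 16.4 ± 0.583 RPKM (1.69, adjusted p = 0.0118), and a predicted gene shares 68.7% of its exonic bases. Acvrl1, a receptor of the TGF-beta family, went from 15.6 ± 2.57 to 46.6 ± 3.397 RPKM (1.53, adjusted p = 0.0118), and Tmem176b from 80.2 ± 23.9 to 213 ± 26.2 (1.43, adjusted p = 0.0257). Adgrg3, Cacnb3, Hap1 and Pdlim4 rose by 1.53, 1.46, 1.46 and 1.44 from WT means of 2.84, 5.06, 4.28 and 3.80 RPKM, with Adgrg3 and Pdlim4 at 0.93 and 0.94 with a pseudocount of 5.

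Among the genes that fell, Nrbp2 went from 16.5 ± 0.498 to 3.83 ± 0.921 RPKM (log2 fold change -1.88, adjusted p = 0.0125), and Dio3os, a long non-coding RNA, from 5.98 ± 0.573 to 0.358 ± 0.225 (-2.37, adjusted p = 0.0118). The log2 fold change of Dio3os was -3.83 with a pseudocount of 0.1 and -1.03 with 5. The other genes with the largest changes were microRNA hairpins with few reads. Mir6903, Mir374c, Mir7675, Mir7080, Mir6926, Mir7005, Mir31 and Mir301 had 1 to 6 reads per WT library and were listed at 0 in miR-27 Tg, and Mir19b-2 had 1 read in each miR-27 Tg library and was listed at 0 in WT. Other annotated transcripts cover 100% of the bases of Mir31, Mir374c and Mir7080. Mir17, which lies within its host transcript Mir17hg, had 7, 7 and 7 reads in WT and 18, 23 and 22 in miR-27 Tg. Of the 140 genes 17 were transcripts of under 200 bases.

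Each library left out moved the counts by over 1.5 times. Without WT replicate 1, 2 or 3, the genes that were higher and lower numbered 5 and 6, 19 and 46, and 3 and 2, and without miR-27 Tg replicate 1, 2 or 3 they numbered 21 and 34, 12 and 44, and 3 and 2. Of 45 genes picked by the naming rule that passed, Mir27a, Oas2 and Itgae passed in each of these 6 fits, with adjusted p of at most 5.51e-05, 0.0134 and 0.0494.

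**Figure D1:**
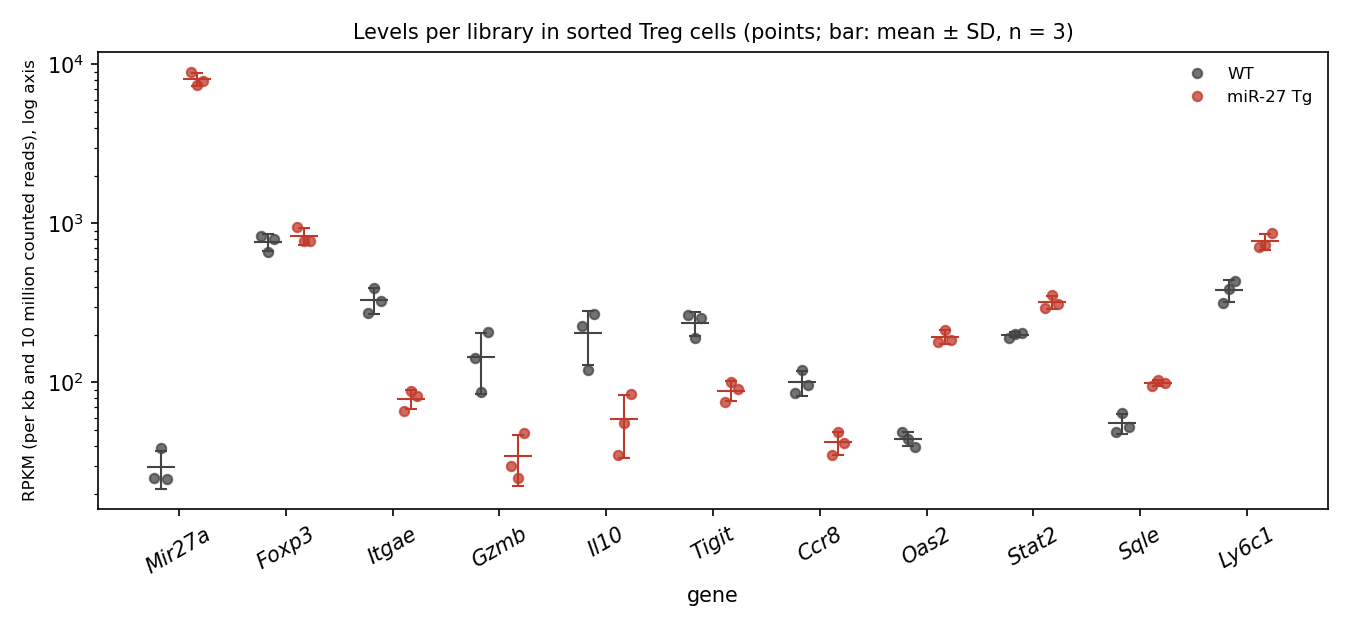
RPKM (per kilobase and 10000000 counted reads, log axis) of 11 genes in each WT and miR-27 Tg library, with the mean and SD of each group of 3. The miR-27 Tg libraries lie above WT for Mir27a, Oas2, Stat2, Sqle and Ly6c1 and below WT for Itgae, Gzmb, Il10, Tigit and Ccr8, while the groups overlap for Foxp3.

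Genes of effector Treg cells were lower as a group by camera with the preset correlation, with a median log2 fold change of -0.59 (adjusted p = 4.47e-16, and adjusted p = 0.152 with an estimated correlation and 0.0226 by fry). Of 31 members 5 fell, 0 rose and 26 did not pass, 29 had a fold change below 0, and 19 fell and 1 rose (Myb) when adjusted over the list alone. Besides Itgae and Gzmb, Tigit, a co-inhibitory receptor, went from 236 ± 40.5 to 88.9 ± 12.5 RPKM (log2 fold change -1.39, adjusted p = 0.0177). Ccr8, a chemokine receptor, went from 100.1 ± 17.6 to 41.9 ± 6.90 RPKM (-1.23, adjusted p = 0.0257), and Rora, a nuclear receptor, from 59.0 ± 3.81 to 27.2 ± 6.13 (-1.11, adjusted p = 0.0292).

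Suppressor molecules of Treg cells were also lower as a group by that test, with a median of -0.55 (camera adjusted p = 1.24e-07, adjusted p = 0.152 with an estimated correlation and 0.0191 by fry). Of 21 members 4 fell (Tigit, Areg, Itgb8 and Gzmb), 0 rose and 17 did not pass, and 10 fell when adjusted over the list alone. Areg, a growth factor of epithelial repair, went from 47.2 ± 5.96 to 21.996 ± 2.58 RPKM (-1.07, adjusted p = 0.0257), and Itgb8, an integrin chain that activates TGF-beta, from 42.6 ± 8.30 to 19.2 ± 1.26 (-1.09, adjusted p = 0.0315).

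The Treg core signature had a median of -0.24. Itgae fell, the other 25 members did not pass, and 3 rose and 6 fell when adjusted over the list alone. Cd83 had 254 ± 68.6 and 110.5 ± 23.0 RPKM in WT and miR-27 Tg (adjusted p = 0.0533), Penk, the enkephalin precursor, 128 ± 9.85 and 53.3 ± 19.4 (0.0699, and 0.0317 without miR-27 Tg replicate 1), and Ctla4, an inhibitory receptor, 3436 ± 324 and 2335 ± 234 (0.0868). The core list had adjusted p = 0.00305 by camera, 0.0981 by fry and adjusted p = 0.426 with an estimated correlation.

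Homing and chemokine receptors had a median of -0.23, and -0.38 without miR-27 Tg replicate 2. Itgae, Ccr8 and Itgb8 fell, 23 of 26 members did not pass, and 2 rose and 8 fell when adjusted over the list alone. Ccr6, a chemokine receptor, had 193 ± 31.7 and 100.4 ± 24.8 RPKM (adjusted p = 0.0787). Adjusted p was 0.00180 by camera and 0.0555 by fry, and adjusted p = 0.293 with an estimated correlation.

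Among helper T cytokines and regulators, Ifng, the type II interferon, fell from 65.0 ± 13.2 to 28.3 ± 5.05 RPKM (log2 fold change -1.17, adjusted p = 0.0343). The other 21 members did not pass, and 1 rose and 3 fell when adjusted over the list alone. Il17a had 9.37 ± 3.51 and 1.99 ± 1.74 RPKM (adjusted p = 0.164) and Il12rb2 3.26 ± 0.809 and 6.17 ± 0.647 (0.178). The helper list had a median of -0.24 and adjusted p = 0.0488 by camera and 0.0981 by fry, with adjusted p = 0.293 with an estimated correlation. The call ended without WT replicate 1 (median -0.12, adjusted p = 0.218) and without miR-27 Tg replicate 3 (-0.14, 0.0864). It also ended with a pseudocount of 0.1 (adjusted p = 0.0526), no filter (0.0715), array weights (0.0739, median -0.11) and no trend (0.0687), and the median was -0.13 with a pseudocount of 5.

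Immediate-early and heat shock genes had a median of -0.24, which was -0.16 without WT replicate 1 and -0.43 without WT replicate 2. Klf6, a transcription factor, fell from 1544 ± 295 to 825 ± 42.5 RPKM (-0.89, adjusted p = 0.0350), and Btg2, an antiproliferative factor, from 1132 ± 92.4 to 782 ± 19.8 (-0.53, adjusted p = 0.0453). The other 26 members did not pass, and 6 fell when adjusted over the list alone. Hspa1b, an inducible chaperone, had 598, 76.2 and 234 RPKM in WT replicates 1 to 3 and 40.3, 46.2 and 30.9 in miR-27 Tg (adjusted p = 0.131), and its near-identical copy Hspa1a had 259, 27.7 and 95.4 and 12.4, 15.8 and 12.7 (0.134). Without WT replicate 2 they had adjusted p of 0.0227 and 0.0227. By camera the list had adjusted p = 0.000294, by fry 0.297, and adjusted p = 0.501 with an estimated correlation.

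Interferon response genes had a median log2 fold change of 0.52 and were higher as a group by camera with the preset correlation alone (adjusted p = 4.47e-16), against adjusted p = 0.265 with an estimated correlation and 0.0924 by fry. Of 29 members 2 rose, 0 fell and 27 did not pass, 26 had a fold change above 0, and 20 rose when adjusted over the list alone. Stat2, which carries type I interferon signals to the nucleus, went from 199.5 ± 7.57 to 320.0 ± 29.7 RPKM (0.68, adjusted p = 0.0258), and Oasl2 from 38.9 ± 5.93 to 94.4 ± 28.2 (1.23, adjusted p = 0.0453). Rtp4 had 136 ± 16.5 and 267 ± 64.5 RPKM (adjusted p = 0.0602, and 0.0311 without miR-27 Tg replicate 1) and Ifit2 170.4 ± 26.4 and 245 ± 13.5 (0.1004, and 0.0486 without WT replicate 2).

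Genes of cholesterol and fatty acid metabolism were higher as a group by camera with the preset correlation, with a median of 0.38 (adjusted p = 2.96e-09, and adjusted p = 0.152 with an estimated correlation and 0.0191 by fry). Of 27 members 2 rose, 0 fell and 25 did not pass, and 9 rose and 1 fell (Abca1) when adjusted over the list alone. Sqle, an enzyme of cholesterol synthesis, went from 55.3 ± 7.95 to 99.0 ± 4.11 RPKM (0.84, adjusted p = 0.0292). Fdps had 40.7 ± 5.25 and 62.0 ± 7.76 RPKM (adjusted p = 0.118).

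Genes of resting and naive-like T cells had a median of 0.18. Ly6c1 rose from 380.0 ± 60.1 to 770.3 ± 87.5 RPKM (1.02, adjusted p = 0.0257), the other 22 members did not pass, and 3 rose when adjusted over the list alone. S1pr1, a receptor for exit from lymph nodes, had 1019 ± 119 and 1418 ± 100.5 RPKM (adjusted p = 0.105), and Bcl2 516 ± 10.9 and 603 ± 34.2 (0.292). The resting list had adjusted p = 1.60e-05 by camera, 0.0981 by fry and adjusted p = 0.265 with an estimated correlation.

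Markers of myeloid cells, which a sort of CD4+Foxp3+ cells is meant to leave out, were also higher as a list in miR-27 Tg by camera with the preset correlation (adjusted p = 4.65e-08), against adjusted p = 0.265 with an estimated correlation and 0.0843 by fry. Their median log2 fold change was 1.17, and 0.75 without WT replicate 1 and 0.65 without miR-27 Tg replicate 2. Itgam rose, the other 15 members did not pass, and 3 rose when adjusted over the list alone. S100a9 had 18.2 ± 21.1 and 94.6 ± 64.9 RPKM (adjusted p = 0.156), Lyz1 6.81 ± 5.10 and 22.1 ± 5.94 (0.172) and Csf1r 11.03 ± 4.65 and 23.0 ± 7.10 (0.247). The mean log2 level of the 16 markers was 4.49, 4.32 and 5.05 in WT replicates 1 to 3 and 5.11, 6.37 and 5.78 in miR-27 Tg replicates 1 to 3, that of effector genes 7.13, 7.09 and 7.17 and 6.17, 6.55 and 6.47, and that of interferon genes 7.55, 7.93 and 7.68 and 7.98, 8.501 and 8.25. The marker level was lower in every WT library than in every miR-27 Tg library. A fit with that level as a covariate therefore separates it poorly from genotype, and calls lost there do not show myeloid RNA as the cause. With the marker level as a covariate in limma, chosen after seeing the data, 1 gene was higher (Mir27a) and 0 were lower. In that fit 997 genes had an unadjusted p under 0.05, against 1773 without the covariate. Oas2 and Itgae then had log2 fold changes of 2.03 and -2.26, against 2.11 and -2.05 without it, with adjusted p of 0.104 and 0.119. Ifitm3 and Oasl2 had log2 fold changes of 0.97 and 0.74 in that fit. Interferon genes then had a median of 0.22, effector genes -0.89, homing genes -0.43, resting genes 0.27 and cholesterol genes 0.25, each list still past the camera threshold with the preset correlation. With an estimated correlation these 5 lists had adjusted p of 0.265, 0.152, 0.293, 0.265 and 0.152 without the covariate.

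**Figure D2:**
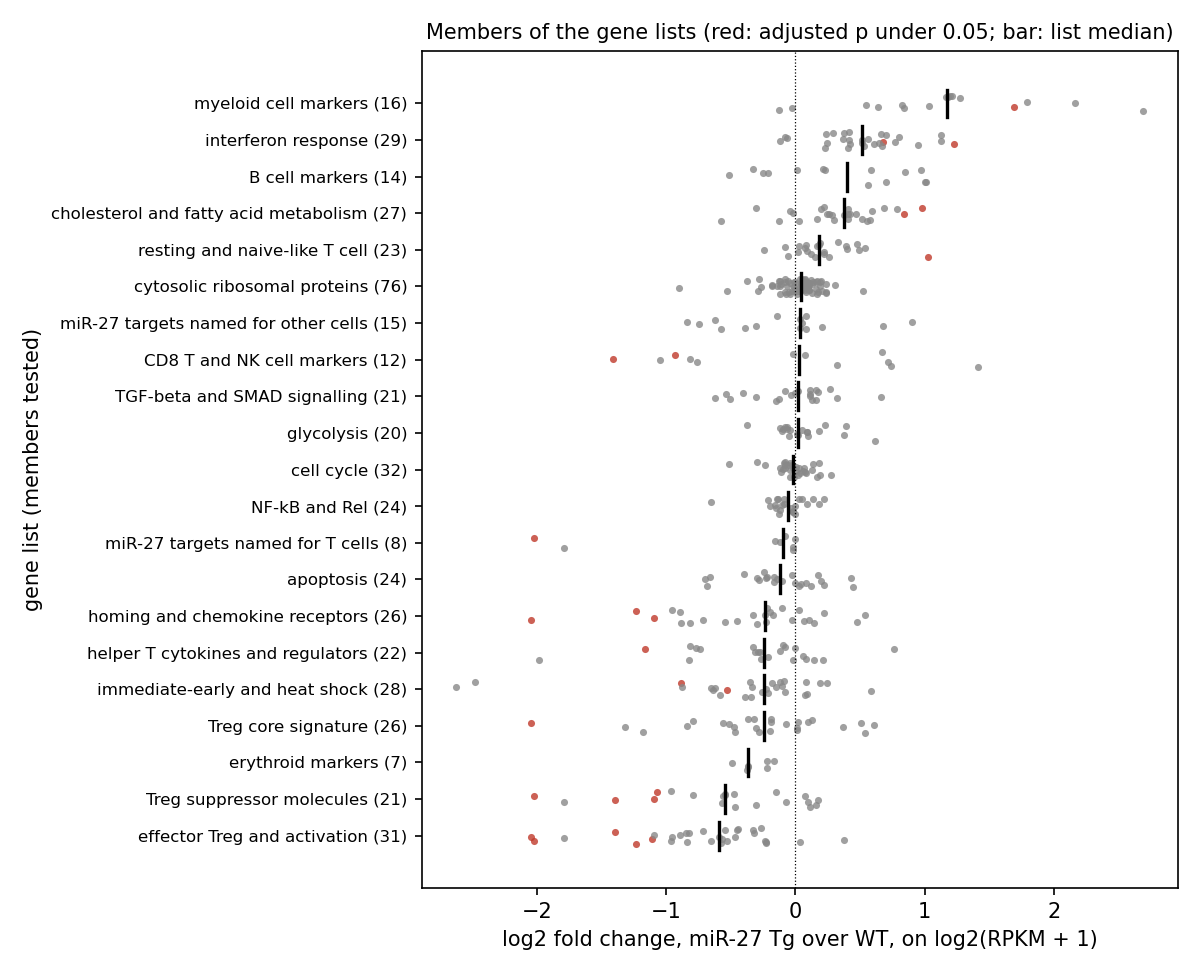
Log2 fold change of miR-27 Tg over WT of each tested member of 21 gene lists, with genes past the threshold in red and the list median as a bar. Among these 21 lists medians run from -0.59 for effector Treg genes to 1.17 for myeloid cell markers. The miR-23/27/24 loci (median 1.71) are not shown.

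Markers of B cells, of CD8 T and NK cells and of erythroid cells did not pass as lists by camera. Of 14 B cell markers 0 passed by limma and 1 had an unadjusted p under 0.05, and the median was 0.40 (adjusted p = 0.0562 by camera, 0.0290 without WT replicate 1, 0.00333 without miR-27 Tg replicate 1 and up to 0.417, with a median of 0.25, without miR-27 Tg replicate 2). That list also passed by camera with a replicate block (adjusted p = 0.0231), array weights (0.0138) and transcripts of under 200 bases left out (0.0453). Cd74 had 705 ± 305 and 1350.2 ± 805 RPKM, Cd79b 99.1 ± 15.2 and 78.9 ± 13.6 and Fcer2a 3.02 ± 1.49 and 4.80 ± 0.741. Of 12 markers of CD8 T and NK cells, Xcl1, a chemokine, fell from 23.1 ± 2.02 to 8.15 ± 1.59 RPKM (-1.41, adjusted p = 0.0238), and Nkg7, a granule protein, from 102 ± 11.6 to 53.0 ± 5.52 (-0.93, adjusted p = 0.0257). Ccl5 had 78.9 ± 16.1 and 43.9 ± 4.24 RPKM (adjusted p = 0.0726) and Klrb1c 5.56 ± 2.19 and 2.07 ± 0.125 (0.140). Adjusted over the list alone, 2 of these markers rose and 5 fell, the median was 0.025 while the mean was -0.089 and camera pointed down (adjusted p = 0.3004). Of 7 erythroid markers 0 passed by limma and 0 had an unadjusted p under 0.05 (adjusted p = 0.476 by camera). Hba-a1 had 6.95 ± 5.597 and 5.54 ± 5.31 RPKM, Hba-a2 6.30 ± 5.27 and 4.997 ± 5.65, and Hbb-b2 and Hbb-bt, which hold identical values, 4.99 ± 3.62 and 3.503 ± 2.27.

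Genes of apoptosis, cell cycle and glycolysis did not pass as lists by camera, and 0 of their members passed by limma. At an unadjusted p under 0.05, 2 apoptosis genes were higher and 4 lower, 0 and 2 of cell cycle and 2 and 1 of glycolysis, and 0 passed when adjusted over the list alone. Apoptosis genes (median -0.12, adjusted p = 0.265 by camera) included Pmaip1 at 137 ± 24.5 and 83.5 ± 13.9 RPKM, Fasl at 29.8 ± 1.89 and 18.8 ± 4.17 and Bid at 101 ± 16.5 and 75.9 ± 4.57. Cell cycle genes (median -0.015, adjusted p = 0.999) included Mcm6 at 341 ± 12.999 and 277 ± 11.3 RPKM, Tk1 at 64.1 ± 12.1 and 44.7 ± 9.44, Birc5 at 56.3 ± 4.99 and 63.5 ± 5.57 and Mcm7 at 128 ± 21.6 and 145 ± 10.9. Glycolysis genes (median 0.017, adjusted p = 0.246) included Eno1 at 309 ± 38.1 and 405 ± 53.6 RPKM, Hif1a at 441 ± 96.2 and 335 ± 11.99, Aldoc at 8.99 ± 1.96 and 14.4 ± 3.70 and Slc16a3 at 17.6 ± 4.15 and 22.8 ± 2.03.

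TGF-beta, NF-kB and ribosomal protein genes did not pass as lists by camera either. By fry the lists that did not pass by camera had adjusted p of 0.0555 to 0.889. In its mixed form, where members may move either way, fry gave adjusted p of 0.000203 for CD8 T and NK cell markers and 0.00108 for targets named for other cells. It gave 0.0157 for TGF-beta and 0.0157 for apoptosis genes, and 0.0555 to 0.749 for the others that did not pass by camera. The TGF-beta, NF-kB and ribosomal lists had 0 members past the threshold by limma. At an unadjusted p under 0.05, 3 TGF-beta genes were higher and 3 lower, 0 and 1 of NF-kB and 1 and 1 of ribosomal proteins. TGF-beta and SMAD genes had a median of 0.019 and a mean of -0.025, and camera pointed up (adjusted p = 0.999). Tgfbr1, a receptor of TGF-beta, had 208 ± 24.99 and 134 ± 11.1 RPKM (adjusted p = 0.0590) and was the 1 member that fell when adjusted over the list alone, beside Smad5 at 70.9 ± 4.19 and 89.0 ± 1.79, Acvr2a at 35.1 ± 6.39 and 24.2 ± 2.18 and Bmpr1a at 5.38 ± 0.698 and 3.39 ± 0.467. NF-kB genes had a median of -0.061 (adjusted p = 0.3004 by camera, 0.0183 without WT replicate 2 and up to 0.872 without another library). Bcl2a1b had 215 ± 30.1 and 136 ± 14.4 RPKM (adjusted p = 0.0657) and was the 1 that fell when adjusted over the list alone, beside Malt1 at 287 ± 14.3 and 249 ± 21.9, Bcl3 at 154 ± 26.1 and 179 ± 14.9 and Relb at 213 ± 7.77 and 195 ± 10.9. Ribosomal protein genes had a median of 0.045 and adjusted p = 0.209 by camera, which was 0.00846 without WT replicate 2, 0.00474 without miR-27 Tg replicate 1 and 0.0354 without miR-27 Tg replicate 2, and up to 0.516 without another library. Rps2 had 855 ± 110.4 and 1226 ± 125 RPKM, Rpl10 126 ± 8.83 and 104 ± 14.8, Rpl36a 12.4 ± 1.45 and 9.33 ± 1.32 and Rpl39l 4.69 ± 1.19 and 2.38 ± 1.996, and 0 members passed when adjusted over the list alone.

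The third comparison asked whether transcripts that miR-27 can bind were lower. Of 8 miR-27 targets named for T cells, Gzmb fell and the other 7 did not pass. Il10, the suppressive cytokine, had 204 ± 76.0 and 58.7 ± 25.003 RPKM in WT and miR-27 Tg (log2 fold change -1.79, SE 0.36, adjusted p = 0.0759 by limma, 0.0495 without WT replicate 2), and it fell with Gzmb when adjusted over the list alone. Rel had 211 ± 22.7 and 208 ± 22.9 RPKM, Runx1 106 ± 19.2 and 94.5 ± 9.94, Smad2 57.6 ± 5.96 and 57.5 ± 1.43, Smad3 137 ± 17.4 and 130.0 ± 15.3, Gata3 187 ± 28.8 and 173 ± 30.9 and Il4 4.04 ± 1.69 and 4.29 ± 2.77, with adjusted p of 0.972, 0.744, 0.999, 0.871, 0.840 and 0.993. Camera gave the list adjusted p = 0.0534, and 0.00532 without WT replicate 2 and 0.0153 without miR-27 Tg replicate 1, and up to 0.274 without another library. It also passed by camera with a replicate block (adjusted p = 0.0231), array weights (0.0336) and a mean RPKM of at least 5 (0.0241). So it did with the mean over transcripts (0.0406) and with transcripts of under 200 bases left out (0.0443). The study may have chosen these genes on these samples, so the list is not independent evidence.

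For 15 tested targets named for other cells the median was 0.034, the mean -0.10 and the camera direction down (adjusted p = 0.212, and 0.0271 with a median of -0.12 without WT replicate 2, and up to 0.593 without another library). By limma 0 passed, 1 was higher and 4 lower at an unadjusted p under 0.05, and 4 fell when adjusted over the list alone. These were Tgfbr1, St14, Abca1 and Zbtb10, with log2 fold changes of -0.62, -0.84, -0.57 and -0.74 and adjusted p over all genes of 0.0590, 0.104, 0.155 and 0.193.

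Across the transcriptome, 2097 of 12190 searched genes carried at least 1 match to bases 2 to 8 of miR-27 in the 3′ UTR. Their median log2 fold change was -0.064, against -0.00015 in the other genes, and 63.6% of them lay below 0, against 50.0%. Genes with 2 or more sites (338 genes) had a median of -0.091 and genes with an 8mer site (755) a median of -0.086. The other 1342 site genes, which lack an 8mer, had a median of -0.045 and did not pass by camera (p = 0.0848, and p = 0.379 with an estimated correlation). Camera gave p = 0.00699 for all site genes, 0.000357 for 2 or more sites and 0.000433 for 8mer sites, and p = 0.172, 0.111 and 0.0614 with an estimated correlation. Over the 10 seeds searched the miR-27 p became 0.0699 after adjustment, and the other 9 seeds had unadjusted camera p of 0.153 to 0.856. Random gene sets matched on 3′ UTR length and expression had a mean median of -0.0064 (95% range -0.013 to 3.76e-05, permutation p = 0.0002, the smallest that 10000 draws can give), but sites of miR-23, miR-181 and miR-21 (lower than their matched sets) and of miR-24 (higher) reached the same p.

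With the preset correlation, the camera call for miR-27 sites ended without WT replicate 1 (difference in medians -0.038, p = 0.0992), with the myeloid marker level as a covariate (-0.029, p = 0.203) and for any 6mer site (-0.028, p = 0.1997), against -0.063 for all site genes. Of 75 searched genes that fell, 21 (28.0%) had a site, against 17.2% of all searched genes (two-sided Fisher's exact test, odds ratio 1.88, 95% confidence interval 1.08 to 3.17, p = 0.0200). Of 44 that rose, 7 (15.9%) had one (Fisher's exact test, p = 1). Fisher's test takes genes as independent of each other, and these sets were not matched on 3′ UTR length or expression. Among genes with a site, Cldnd1, a membrane protein, fell from 192 ± 8.29 to 106 ± 5.17 RPKM (adjusted p = 0.0118 by limma), and Plscr1, a phospholipid scramblase, from 49.7 ± 7.90 to 20.1 ± 1.4998 (0.0195). Sh3bgrl2, Mmd and Vsig10 fell by 1.37, 0.93 and 1.16 on the log2 scale, with adjusted p of 0.0257, 0.0257 and 0.0257. Itgae, Gzmb, Tigit and Il10 had 0 such sites, and Rora had 3.

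**Figure D3:**
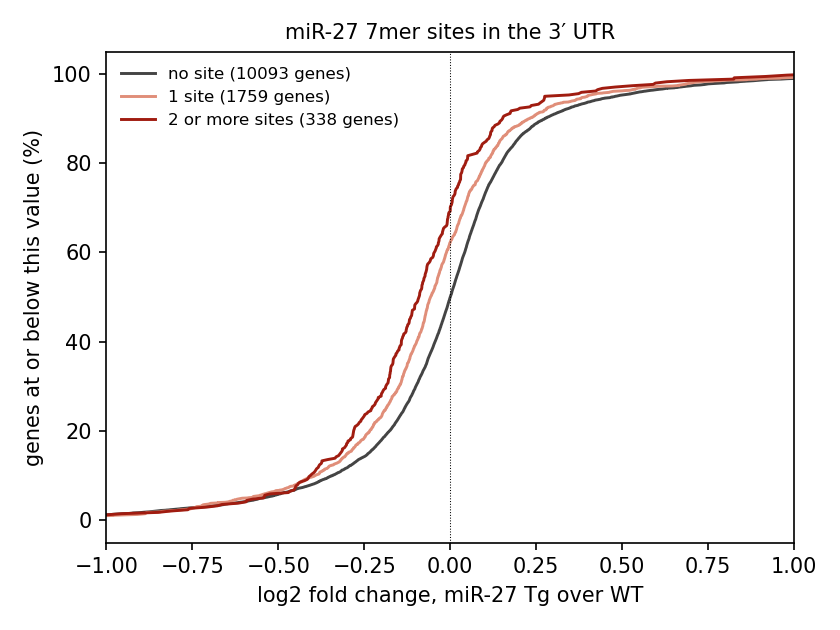
Cumulative share of genes (percent) by log2 fold change of miR-27 Tg over WT, for 10093 genes without a miR-27 site in the 3′ UTR, 1759 with 1 site and 338 with 2 or more. The medians are -0.00015, -0.057 and -0.091.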

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

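Leaving out transcripts of under 200 bases and adding the myeloid marker level as a covariate were chosen after seeing the data, and the other alternatives before. All 45 genes of the naming rule past the threshold kept their direction in every alternative that gave them a value, and 1, Mir27a, passed in every such alternative (it is itself under 200 bases). With a library left out, which leaves fewer samples, 16 to 42 of them no longer passed. The number was 44 with the covariate, which overlaps with genotype, 23 without the filter, 8 without the trend and at most 2 in any other alternative. Their log2 fold changes were 0.792 to 1.17 times the main values with a library left out, and 0.546 to 1.35 times with the covariate, but 0.338 to 0.996 times with a pseudocount of 5 and up to 2.48 times with 0.1, where the genes moved by over 1.5 times were Dio3os and hairpins listed at 0 in one group, and with 5 also Adgrg3 and Pdlim4. Of 11 gene lists past the threshold by camera, 10 kept their direction in every alternative and 9 passed in every one but the estimated correlation, the exceptions being the helper T list and the myeloid markers, whose own mean is the covariate that by construction ended their call and turned their median. With the estimated correlation 0 lists were higher and 0 lower by camera (3 of 22 at an unadjusted p under 0.05), and the seed difference of -0.063 no longer passed. Depth limits part of the calls: 12 of the 140 genes called had a mean of 10 reads or fewer in their higher group.

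Counts of higher and lower genes were 15 and 33 with no filter, which tests 18024 genes, 81 and 144 with array weights, 100 and 200 at an adjusted p under 0.10, and 1 and 0 by limma with the myeloid covariate (997 at an unadjusted p under 0.05). Leaving out each library gave 3 to 21 higher and 2 to 46 lower genes. The seed difference was -0.029 with the covariate, -0.028 for any 6mer site and -0.071 to -0.038 with a library left out. Lists that had not passed did so in some alternatives: targets named for T cells in 7, B cell markers in 5, ribosomal proteins in 3, targets named for other cells in 2, and NF-kB, cell cycle and CD8 T and NK cell markers in 1 each. So did genes: Cd83 and Rtp4 in 6, Bcl2a1b in 5, Il10 in 4, Penk in 3, Mir24-2, Mir23b, Ccl5, Ccr6, Hspa1a, Hspa1b, Ifit2 and Tgfbr1 in 2 each, and Mir27b, S1pr1 and Ctla4 in 1 each. Except where fewer samples or more genes were tested, the cause was not tested.

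With the replicate number as a block, 91 genes were higher and 185 lower, among them 49 and 87 of those called without it. Deviations from the group means correlated at 0.368, 0.0971 and 0.0368 for equal numbers 1, 2 and 3. WT replicate 2 correlated best with miR-27 Tg replicate 3 (0.154) and WT replicate 3 with miR-27 Tg replicate 2 (0.119). The numbers were therefore not taken to pair all libraries, but WT replicate 1 and miR-27 Tg replicate 1 varied alike. On principal component 2 of the log2 levels (25.7% of the variance) they lay at 20.3 and 32.8. The other libraries lay at -18.7 to -8.04. What these replicates share was not tested, and the main fit leaves it in the residual spread behind its p-values.

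Signs turned for values that had not passed the test, and the cause was not tested, except for the myeloid markers and the members of that list with the covariate. With a pseudocount of 5 the CD8 T and NK cell median was -0.00052 and Il4 0.012. With a mean RPKM of at least 5 the CD8 T and NK cell median was -0.39 and that of targets named for other cells -0.31. Median-of-ratios scaling gave 0.017 for cell cycle, 0.014 for Rel, 0.0022 for Il4 and 0.0094 for Cst3, and quantile normalization 0.037 for cell cycle and 0.036 for Il4. Array weights gave 0.051 for cell cycle, -0.0076 for targets named for other cells, 0.064 for Rel and 0.17 for Il4, and the mean over transcripts -0.0028 for Smad2. With the myeloid covariate the medians were -0.63 for B cell, -0.45 for CD8 T and NK cell and -0.27 for myeloid cell markers, 0.11 for cell cycle, -0.047 for ribosomal proteins and -0.39 for targets named for other cells, with Mir23a at 2.202, Rel at 0.12, Cd74 at -0.71, Rpl39l at 0.47, Lyz2 at -0.35 and Tyrobp at -1.42. With a library left out, medians ran from -0.32 to 0.26 for CD8 T and NK cell markers, -0.78 to 0.16 for erythroid markers, -0.089 to 0.067 for cell cycle, -0.064 to 0.12 for ribosomal proteins, -0.16 to 0.032 for targets named for other cells, -0.074 to 0.083 for TGF-beta, -0.019 to 0.060 for glycolysis and -0.10 to 0.0029 for NF-kB. Log2 fold changes then ran from -0.41 to 0.38 for Il4, -0.11 to 0.075 for Rel, -0.048 to 0.083 for Smad2, -0.19 to 0.011 for Smad3, -0.25 to 0.020 for Gata3, -0.73 to 0.53 for Mir23a, -0.17 to 0.16 for Cst3, -0.23 to 0.018 for Ctss, -1.01 to 0.18 for Hba-a1, -1.23 to 0.11 for Hba-a2, and -0.75 to 0.094 for both Hbb-b2 and Hbb-bt.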

Other observations

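Genes in the next paragraph, the tests of effector genes without a site, of Foxp3, of chromosome 5 and of correlated myeloid markers, and Oas3, Rasal1 and Aldh2, were chosen after the values were seen.

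Outside the lists further genes passed the test. Cst7, an inhibitor of cathepsins, went from 389 ± 91.8 to 127 ± 15.9 RPKM (n = 3, log2 fold change -1.59, adjusted p = 0.0134 by limma). Il18r1, a chain of the IL-18 receptor, went from 319 ± 31.6 to 170.5 ± 18.2 RPKM (adjusted p = 0.0221), Tnfrsf8, which encodes CD30, from 26.8 ± 3.30 to 11.9 ± 2.32 (0.0394), Cd101 from 113 ± 13.2 to 59.0 ± 7.42 (0.0279), and Ahr, a ligand-activated transcription factor, from 59.4 ± 3.11 to 34.9 ± 4.86 (0.0446). Adora2a, Tox2, Hpgds, Src and Cpt1a fell by 0.56, 1.01, 1.36, 1.20 and 0.54 on the log2 scale. Among higher genes, Trib2 went from 655 ± 10.2 to 986 ± 58.0 RPKM (adjusted p = 0.0259), Ms4a4c from 137 ± 15.2 to 259.9 ± 32.3 (0.0257), Itgb3, an integrin chain, from 95.9 ± 3.95 to 137 ± 5.25 (0.0437) and Card9, an adaptor of innate signalling, from 17.3 ± 1.68 to 33.6 ± 3.82 (0.0371). Sox4 went from 27.2 ± 5.54 to 57.9 ± 6.28 RPKM (adjusted p = 0.0350), and a predicted gene shares 54.6% of its exonic bases. Of the 20 genes past the threshold that were chosen in this way, 1, 8 and 0 passed by limma without WT replicate 1, 2 or 3, 7, 5 and 0 without miR-27 Tg replicate 1, 2 or 3, and 0 with the myeloid marker level as a covariate, where 997 of all genes had an unadjusted p under 0.05. With no filter on low values 6 of them passed, without the trend 10, and at least 17 in each other alternative. With the covariate the log2 fold changes of these genes were 0.706 to 1.35 times those without it, and 0 changed sign. Gsg2, which lies within the span of Itgae, fell by 1.399, and Cpne7, whose exons contain Mir7080, fell by 1.69.

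Effector Treg genes had a median log2 fold change of -0.59 (5 of 31 fell, and the call by camera ended at adjusted p = 0.152 with an estimated correlation), which repression of each gene by miR-27 sites, dilution by RNA of other cells or handling stress could produce. The 24 members with a searched 3′ UTR and no 7mer site had a median of -0.77 (quartiles -0.99 to -0.46), and the 7 with a site had -0.45. The 15 members without a 6mer site had -0.84. This argues against repression through 7mer sites of the searched 3′ UTRs as the whole cause. It does not address sites elsewhere in the transcripts, which were not searched. Gzmb and Il10, which are named as miR-27 targets for T cells, are among the 24. Foxp3 had a log2 fold change of 0.13 (-0.12 to 0.38 at 2 SE), although 31.5% of its exonic bases are shared with other genes. This argues against dilution by RNA of cells without Foxp3 as the source of the list's whole change. The level of Foxp3 cannot tell a change per cell from a change in the mix of Foxp3+ cells, which was not tested. With the stress score of each library as a covariate the median was -0.65 (quartiles -1.08 to -0.45), beyond the bound of -0.2 set for stress as the cause, while the same covariate took the medians of interferon, cholesterol and resting genes from 0.52, 0.38 and 0.18 to 0.27, 0.23 and 0.35. The genotype itself stays among the open explanations, as untested.

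Interferon response genes had a median of 0.52 (2 of 29 rose, adjusted p = 0.265 with an estimated correlation and 0.0924 by fry), among them Oasl2 on chromosome 5, where Oas2, which is not in the list, also lies. The 27 members on other chromosomes had a median of 0.52 (quartiles 0.33 to 0.67). This argues against a segment of chromosome 5 carried with one genotype as the cause for the list through genes within the segment alone. An effect of such a segment on genes of other chromosomes was not tested. For Oas2 and called genes near it (Vsig10, Rasal1, Oas3 and Aldh2) that cannot be told apart from an expression change: the window of 5 Mb held 5 called genes, against 3 to 6 in 95% of 10000 random sets (median 4), a number that neither stands out nor lies at the median. With the myeloid marker score as a covariate the list median was 0.22 (quartiles 0.13 to 0.33). The rule set beforehand counted a median of at least 0.2, with a positive lower quartile, against myeloid RNA. These values met that rule, but the median passed 0.2 by less than the spread of the quartiles, so no conclusion was drawn. RNA of myeloid cells stays open as the source, as do handling stress, with whose score as a covariate the median was 0.27, and the genotype itself, which was not tested.

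Myeloid markers had a median of 1.17 although the sort took CD4+Foxp3+ cells (1 of 16 rose, adjusted p = 0.265 with an estimated correlation and 0.0843 by fry). Within groups the 16 markers varied together across libraries, with a mean pairwise correlation of 0.48. In 95% of 10000 random sets matched on level it was -0.053 to 0.24. The correlation that camera estimated was higher still for interferon (0.59), immediate-early and heat shock (0.55), ribosomal protein (0.64) and erythroid genes (0.88), and lower for the other lists. The result therefore cannot tell differing amounts of myeloid RNA from genes that vary together for another reason. Tyrobp had 32.3, 86.4 and 167 RPKM in WT replicates 1 to 3 and 51.7, 415 and 249.9 in miR-27 Tg, and Lyz2 131, 91.9 and 277 and 196, 501 and 405. The most abundant markers, Ctss at 1481 ± 193 and 1365 ± 229.8 RPKM and Cst3 at 373 ± 66.6 and 369 ± 78.0, had adjusted p of 0.808 and 0.979 by limma. Whether such levels hide RNA of a small share of other cells was not tested. Itgam had a log2 fold change of 1.69 (SE 0.16). With the score of the other markers as a covariate it was 1.55 (SE 0.28, adjusted p = 0.162 by limma), where the call of Itgam ended because the SE grew. The score thus accounted for little of the change. It overlaps with genotype, however, and averages markers that did not move alike, such as Ctss and Cst3. The fit therefore cannot decide whether myeloid RNA was the whole source of Itgam. A predicted gene shares 68.7% of the exonic bases of Itgam, so the 2 changes were not separated, and a change within Treg cells was not tested.

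The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The split by genotype called 140 genes and the highest other split 3 (1 of 10 as large). It gave 11 lists by camera with the preset correlation, against 4 to 12 in the other splits (2 of 10 as large). Many lists thus passed under groupings that mix the genotypes, so a passing list is not by itself tied to genotype. Those splits still hold unequal numbers of each genotype per side, so they are not free of its effect. The size of the seed difference was 0.063, against 0.051 in the highest other split (1 of 10 as large).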
